A study of Mus musculus with 12 samples.

How the data were processed

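Total RNA from 12 mouse cell samples had been hybridised by the submitters to Affymetrix arrays whose probe sets use perfect-match probes alone, with 1 array per sample. The labels put 3 arrays in each of 4 groups: hematopoietic cells of C57BL/6 (B6) mice, hematopoietic cells of Ts1Cje mice, and acute myeloid leukaemia (AML) cell lines expressing Trib1 from each of these backgrounds (B6 Trib1 and Ts1Cje Trib1). The deposited values were the intensity of each of 45141 probe sets on a linear scale, which the submitters' processing notes credit to MAS5. MAS5 uses mismatch probes, which arrays of this kind lack, and the notes give no scaling target, so how the values were summarised and scaled was not settled. Probe-level files were not used. Array medians lay between 30.5 and 32.0 and no further scaling was applied in the values reported, a choice on which the balance between higher and lower genes depended. The number of arrays limits the precision.

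Of the probe sets, 28898 carried 1 gene symbol, 551 carried several, 15588 carried none and 104 were controls. Symbols came from the platform table, and for 28689 of the probe sets with 1 symbol the Entrez identifier was found in the reference gene table. No genome build was given in the sources used, and the reference gene table of the mouse assembly GRCm38 served only for current names, chromosomes and neighbouring genes. Control probe sets were left out of every test, and probe sets with no or several symbols were left out of the tests of named genes. The latter were counted from a further fit to all kept probe sets, with or without a single symbol, with p-values adjusted over all of them. A probe set was kept when its intensity exceeded its array's 40th percentile (between 22.0 and 23.5) in at least 3 of the 12 arrays. The values were transformed as log2(intensity + 15), where 15 is the rounded 20th percentile of all deposited values, so that log2 differences of dim genes are drawn towards 0. Each gene was represented by the kept probe set with the highest mean. The filter kept 20066 probe sets for 12560 genes, of which 4845 had several kept probe sets.

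A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances. Its contrasts were Ts1Cje minus B6, Ts1Cje Trib1 minus B6 Trib1, B6 Trib1 minus B6, Ts1Cje Trib1 minus Ts1Cje, and the interaction, which is the genotype difference with Trib1 minus that without it. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 12560 genes of a contrast, and a gene passed at an adjusted p under 0.05 with no minimum fold. Replicate numbers were not used as pairs. Deviations of same-numbered arrays from their group means had correlations across genes from -0.45 to 0.35, and 3 of the 12 arrays resembled their own number best.

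The tests, the named-gene rule, the gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. The 34 lists came from textbook knowledge. They covered secondary and primary granule proteins, monocytes and macrophages, eosinophils, mast cells and basophils, megakaryocytes, erythroid cells, dendritic cells, B cells, T and NK cells, stroma, stem and progenitor cells, and HOX and MEIS genes. Further lists covered the trisomic segment of chromosome 16, distal chromosome 12, sex-linked genes, the C/EBP axis, MAPK feedback, IL-3 and STAT5 targets, the BCL2 family, interferon response, inflammatory NF-kB targets, and MHC class I and class II. The remaining lists covered DNA replication, replication histones, the G2 and M phases, CDK inhibitors with p53 targets, MYC with ribosome biogenesis, oxidative phosphorylation, glycolysis, hypoxia, cholesterol synthesis, and endoplasmic reticulum (ER) with integrated stress. Each list with at least 3 measured members was tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and adjustment over the 34 lists. The test was repeated with the correlation estimated from the data.

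Named genes were Trib1, the 12 largest rises and 12 largest falls of each pairwise contrast among named genes that passed with no overlap between the groups, and up to 4 members with the smallest adjusted p of each list that passed. The same number of members was drawn from the trisomic, distal chromosome 12, C/EBP and interferon lists in any case, and the interaction gave its 6 largest changes in each direction. A subset of these genes is named in the text.

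The alternatives were quantile normalization, median centring, an offset of 1, a floor in place of the offset, no filter, a stricter filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridizing, a variance trend with robust moderation, only the groups compared, the replicate number as a block, an estimated correlation in camera, and each of the 12 arrays left out in turn. A pair of alternatives was added after seeing the data: leaving out Ts1Cje array 1 with B6 Trib1 array 3, and only probe sets with a mean intensity of at least 100. The procedure was tested on simulated data with 200 of 12560 genes changed. For Ts1Cje against B6, it recovered 64% of changes of 0.25 on the log2 scale, 98% of changes equal to the log2 of a ratio of 1.5, and 100% of changes of 1 and of 2. It made 16 false calls among 197 calls and 0 calls in a limma contrast without simulated changes. The simulated noise was independent between genes and between arrays, and far fewer genes were changed than passed in the data. These rates may therefore not hold for the real contrasts.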

Results

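Gene expression was measured on 12 arrays, with 3 arrays in each of 4 groups. Ts1Cje mice carry an extra copy of a segment of chromosome 16 that corresponds to part of human chromosome 21, and B6 mice have the usual number of copies. Trib1 is a pseudokinase that promotes degradation of the transcription factor C/EBP alpha and activates the MEK-ERK pathway. Cells without Trib1 are described only as hematopoietic cells, and those with Trib1 as AML cell lines, all grown with 10% serum and 5 ng/ml IL-3 and profiled from 100 ng of total RNA. Trib1 expression and leukaemic state therefore went together in every comparison of lines with hematopoietic cells. Intensities reached a maximum between 8041 and 8685 on each array, with a median between 30.5 and 32.0, and values near or under the 40th percentile of 22.0 to 23.5 were dim. The 12 pairs of arrays within a group had correlations across genes from 0.997 to 0.999, and the 54 pairs between groups from 0.915 to 0.993. The first principal component, which held 84.5% of the variance, separated the arrays with and without Trib1. All p-values measure only the spread between these arrays, which may be technical, because the labels do not say whether a group's 3 arrays came from separate mice, lines or cultures. Values after the symbol ± are standard deviations of intensities over n = 3 arrays.

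The Trib1 probe set that passed the filter had intensities of 76.2 ± 7.23 in B6, 72 ± 3.5 in Ts1Cje, 46.2 ± 2.88 in B6 Trib1 and 45.9 ± 3.57 in Ts1Cje Trib1. It fell by 0.57 on the log2 scale in the B6 background (adjusted p = 3.33e-06) and by 0.52 in the Ts1Cje background (adjusted p = 7.01e-06). A further Trib1 probe set was dim in all 4 groups, with means of 18.3, 19.7, 18.6 and 18.7. Neither probe set is known to lie within the expressed construct, so these values do not check the Trib1 labels. Between genotypes the Trib1 differences were -0.07 without and -0.01 with the construct (adjusted p = 0.382 and 0.95).

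The comparison of Ts1Cje with B6 cells asked how the trisomy went with expression in cells without Trib1. Genes of granulocytes and macrophages were higher in Ts1Cje cells, and genes of B cells, T cells and progenitors were lower. Lactoferrin (Ltf), an iron-binding protein of neutrophil granules, rose from 1607 ± 7.05 to 3812 ± 163, or 1.24 on the log2 scale. Vpreb1, part of the surrogate light chain of B-cell progenitors, fell from 1881 ± 58.3 to 586 ± 32. The largest rise was that of Dnah11, an axonemal dynein gene of distal chromosome 12, from 72.7 ± 5.06 to 1332 ± 33.6, or 3.94 on the log2 scale (adjusted p = 6.15e-13).

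Of the 18 measured members of the list of secondary granules, which neutrophils make late in maturation, 16 rose and 1 fell, with a median log2 difference of 0.98 (adjusted p = 3.31e-11). Members that rose included Padi4, which citrullinates histones and need not be a granule protein (1.61), Lrg1 (1.78) and Wfdc21 (1.29). Among monocyte and macrophage genes 19 of 22 rose and 1 fell, with a median of 0.70 (adjusted p = 8.55e-10). Coagulation factor F13a1 rose by 1.29 and the complement gene C1qa by 1.18. Primary granule genes rose in 11 of 12 cases (median 0.38, adjusted p = 2.22e-07), including lysozyme Lyz2, from 3743 ± 74 to 5119 ± 49.6. Cholesterol synthesis genes rose in 14 of 19 cases (median 0.30, adjusted p = 1.7e-06), with Fdps, farnesyl diphosphate synthase, up from 2016 ± 27.6 to 3382 ± 28.1. Outside the lists, the neutrophil-related genes Itgb2l (2.16) and Ceacam10 (2.15) and the eosinophil ribonuclease Rnase2a (1.68) were among the largest rises. Itgb2l was at 1.17 with the mean of its probe sets.

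B cell genes fell in 12 of 13 cases (median -1.10, adjusted p = 4.87e-09). Among them, Dntt, the terminal transferase of antigen receptor assembly, fell from 616 ± 19.4 to 159 ± 15.4, and the B-lineage transcription factor Ebf1 fell from 379 ± 23.5 to 95.1 ± 21.4. T and NK cell genes fell in 11 of 15 cases (median -0.80, adjusted p = 1.35e-05), including granzyme A, Gzma (-1.72), and the T-lineage factor Bcl11b (-1.0). Stem and progenitor genes fell in 18 of 22 cases and rose in 2 (median -0.39, adjusted p = 1.33e-05). Cd34 fell from 382 ± 8.28 to 122 ± 13.1 and the homeobox gene Meis1 by 1.33, whereas Prom1 rose by 1.14. With the mean of their probe sets, Bcl11b was at -0.49 and Meis1 at -0.66. Genes of MYC and ribosome biogenesis fell in 24 of 27 cases (median -0.40, adjusted p = 2.11e-09). Dkc1, which modifies ribosomal RNA, fell by 0.54 and the nucleolar gene Nop56 by 0.51.

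The calls of a further set of lists were lost when the correlation was estimated. Megakaryocyte genes fell in 12 and rose in 3 of 17 cases (adjusted p = 0.0605 with an estimated correlation, 0.000119 with the preset one), among them integrin Itgb3, from 807 ± 23.4 to 352 ± 19.8. DNA replication genes fell in 20 and rose in 1 of 30 cases (median -0.26, adjusted p = 0.154 with an estimated correlation), and the polymerase gene Pole fell by 0.53 on the log2 scale. Mast cell and basophil genes rose in 11 and fell in 4 of 19 cases (median 0.35, adjusted p = 0.0605 with an estimated correlation). Fcer1a, a subunit of the IgE receptor, rose from 43.9 ± 2.67 to 246 ± 22.7, and the basophil protease Mcpt8 rose from 1411 ± 29.4 to 2735 ± 129.8. Glycolysis genes rose in 13 and fell in 2 of 18 cases (adjusted p = 0.1 with an estimated correlation), and hypoxia genes rose in 10 and fell in 2 of 21 (adjusted p = 0.1 with an estimated correlation). Aldoc rose by 0.93 (0.51 with the mean of its probe sets) and the mitophagy gene Bnip3 by 1.09. ER and integrated stress genes rose in 16 and fell in 5 of 29 cases (adjusted p = 0.1 with an estimated correlation), and eosinophil genes rose in 3 of 6 (adjusted p = 0.0863 with an estimated correlation). C/EBP axis genes rose in 9 and fell in 3 of 14 cases (adjusted p = 0.1 with an estimated correlation), with Cebpd up from 674 ± 13.1 to 1059 ± 49.9. Stromal genes fell in 7 of 11 cases (adjusted p = 0.0605 with an estimated correlation). Erythroid genes fell in 7 and rose in 2 of 15 cases (adjusted p = 0.103 with an estimated correlation), with the haemoglobin gene Hba-a1 down from 983 ± 17.4 to 471 ± 3.11. MHC class II genes fell in 5 and rose in 1 of 12 cases (adjusted p = 0.248 with an estimated correlation), and CDK inhibitor and p53 genes fell in 10 and rose in 3 of 22 (adjusted p = 0.248 with an estimated correlation).

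In all, 6602 of 12560 genes passed with limma in Ts1Cje against B6, of which 2925 were higher and 3677 lower, and 63 were at least 2-fold higher and 102 at least 2-fold lower. Under median centring of the arrays 4719 were higher and 2538 lower, so the balance between directions is not settled by these data. With camera, 21 of 34 lists passed, 11 up and 10 down, and 9 of them passed with an estimated correlation. For the lists that passed, the counts of members were the same when adjusted over the list alone, except that 35 trisomic genes rose, 18 ER stress genes rose and 6 fell, and 2 DNA replication genes rose and 21 fell. Adjusted over the list alone, 25 MYC and ribosome, 13 megakaryocyte, 3 glycolysis, 5 hypoxia, 9 erythroid, 6 MHC class II and 11 CDK inhibitor genes fell. For the CDK inhibitor list the call was lost without B6 array 1, Ts1Cje array 2 or Ts1Cje array 3 (adjusted p = 0.0505, 0.0718 and 0.0769). It was also lost with the replicate number as a block, quantile normalization and median centring (adjusted p = 0.0528, 0.0797 and 0.0642). The stricter filter and the mean of a gene's probe sets removed it too (adjusted p = 0.209 and 0.203). The MHC class II call was lost without B6 array 2, Ts1Cje array 2 or Ts1Cje array 3 (adjusted p = 0.0559, 0.0652 and 0.0529), and the erythroid call without Ts1Cje array 1 (adjusted p = 0.0844). The C/EBP axis call was lost with Ts1Cje array 1 and B6 Trib1 array 3 left out together (adjusted p = 0.0662), and the stromal call with the stricter filter (adjusted p = 0.0598).

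**Figure D1:**
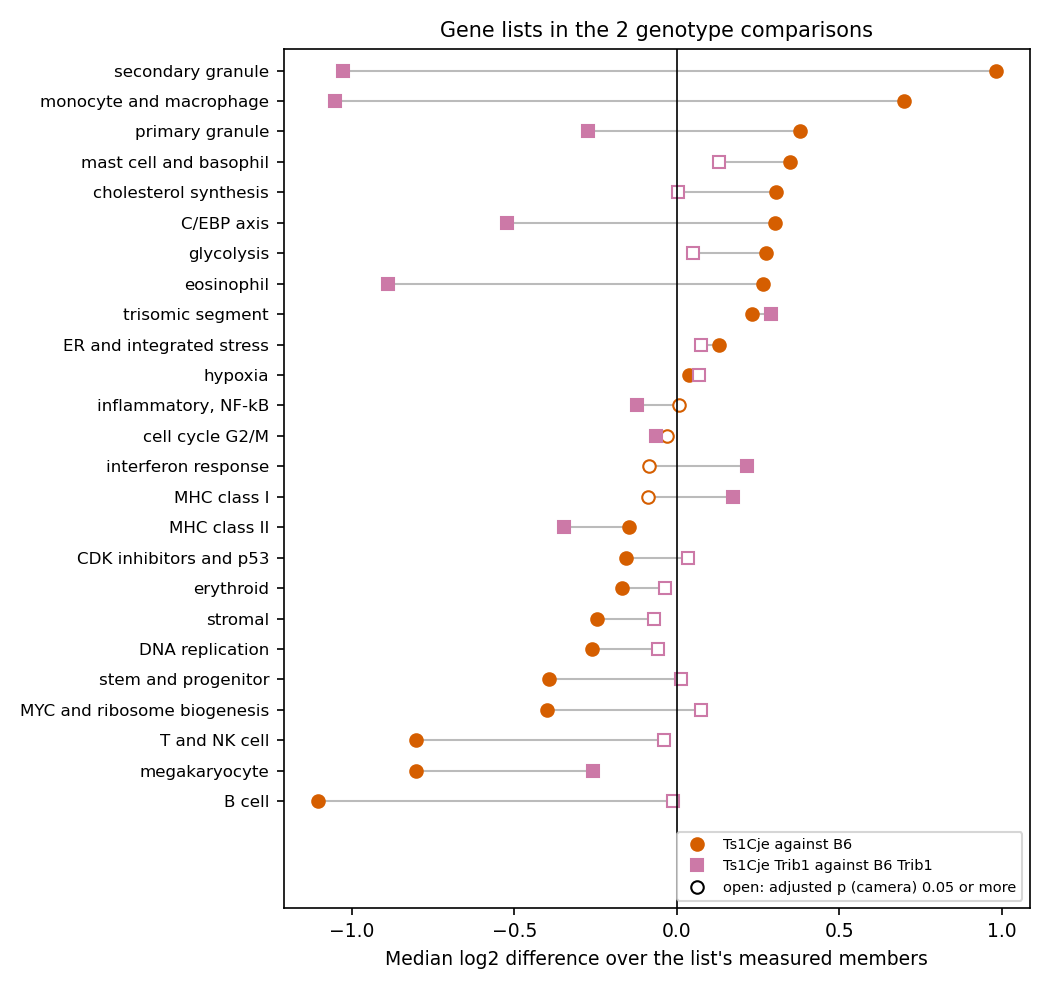
Median log2 difference between the genotypes, on the horizontal axis, for each of the 25 gene lists that passed camera in either genotype comparison; circles give Ts1Cje against B6, squares give Ts1Cje Trib1 against B6 Trib1, and open symbols mark an adjusted p of 0.05 or more. The secondary granule list lies at 0.98 without Trib1 and at -1.03 with it, and the trisomic list at 0.23 and 0.29.

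The comparison of Ts1Cje Trib1 with B6 Trib1 lines asked the same of the leukaemic lines. Genes of granulocytes, macrophages and eosinophils were lower in the Ts1Cje Trib1 lines, and interferon response genes and the trisomic genes were higher. The antimicrobial peptide gene Camp fell from 942 ± 33.7 to 284 ± 26.1, and myeloperoxidase, Mpo, the main peroxidase of neutrophils, fell from 2964 ± 59.4 to 1115 ± 23.3. Usp18, an interferon-induced deubiquitinase, rose from 531 ± 20.7 to 945 ± 22. As in the cells without Trib1, Dnah11 had the largest rise, from 78.4 ± 4.75 to 1310.2 ± 123, or 3.82 on the log2 scale (adjusted p = 9.06e-13).

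Secondary granule genes fell in 17 of 18 cases and rose in 0 (median -1.03, adjusted p = 2.62e-25), including the collagenase gene Mmp8 (-1.71), ficolin Fcnb (-1.62) and Ltf (-1.33). Monocyte and macrophage genes fell in 17 and rose in 2 of 22 cases (median -1.05, adjusted p = 6.22e-18). The endotoxin receptor gene Cd14 fell from 148 ± 6.7 to 45.3 ± 5.22, and the pore-forming gene Mpeg1 fell from 785 ± 16.3 to 256 ± 9.36. Primary granule genes fell in 7 and rose in 2 of 12 cases (median -0.27, adjusted p = 3.9e-05), with neutrophil elastase, Elane, down from 915 ± 32.9 to 257 ± 23.1. Eosinophil genes fell in 5 of 6 cases (median -0.89, adjusted p = 1.23e-07), including the granule protein Prg2 and the peroxidase Epx (-1.43 and -1.69). Among C/EBP axis genes 8 fell and 1 rose of 14 (median -0.52, adjusted p = 3.34e-05). Cebpd fell from 295 ± 8.07 to 106 ± 4.04, Irf8, a factor of monocyte development, fell by 1.16, and Spi1, which encodes PU.1, fell by 0.54.

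Interferon response genes rose in 19 and fell in 3 of 34 cases (median 0.22, adjusted p = 1.32e-07), including Xaf1 (0.60) and Ifi27l2a (0.75). MHC class I genes rose in 8 of 10 cases (median 0.17, adjusted p = 3.59e-05), including their transactivator Nlrc5, from 105 ± 4.7 to 154 ± 7.73. MHC class II genes fell in 7 and rose in 1 of 12 cases (median -0.35, adjusted p = 5e-05 with the preset correlation, and adjusted p = 0.0545 with an estimated correlation), with the invariant chain gene Cd74 down from 1452 ± 46.3 to 1016 ± 73.6. Megakaryocyte genes fell in 9 of 17 cases (median -0.26, adjusted p = 5.97e-06), among them Vwf, von Willebrand factor (-0.60). Inflammatory NF-kB targets fell in 12 and rose in 3 of 29 cases (median -0.12, adjusted p = 9.91e-05), including the chemokine Ccl2, from 393 ± 12.9 to 138 ± 19.9. G2 and M phase genes fell in 6 of 29 cases (median -0.07, adjusted p = 0.215 with an estimated correlation), among them Mki67, which encodes the Ki-67 antigen (-0.22). Beyond the lists, Tgfbi (-2.31), Saa3 (-2.24) and haptoglobin, Hp (-1.91), had the largest falls. Rprm, a p53-induced inhibitor of the cell cycle, rose by 1.66 and the embryonic globin gene Hbb-y by 1.52.

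In this comparison 2698 genes passed, of which 1489 were higher and 1209 lower, and 14 were at least 2-fold higher and 68 at least 2-fold lower. With camera, 12 lists passed, 3 up and 9 down, and 10 of them passed with an estimated correlation. Adjusted over the list alone, 34 trisomic, 21 interferon, 9 MHC class I and 2 C/EBP axis genes rose, and 5 interferon, 11 megakaryocyte, 9 MHC class II, 13 inflammatory and 8 G2 and M phase genes fell, with the other counts for lists that passed as given. The labels do not say how many lines represent each genotype.

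**Figure D2:**
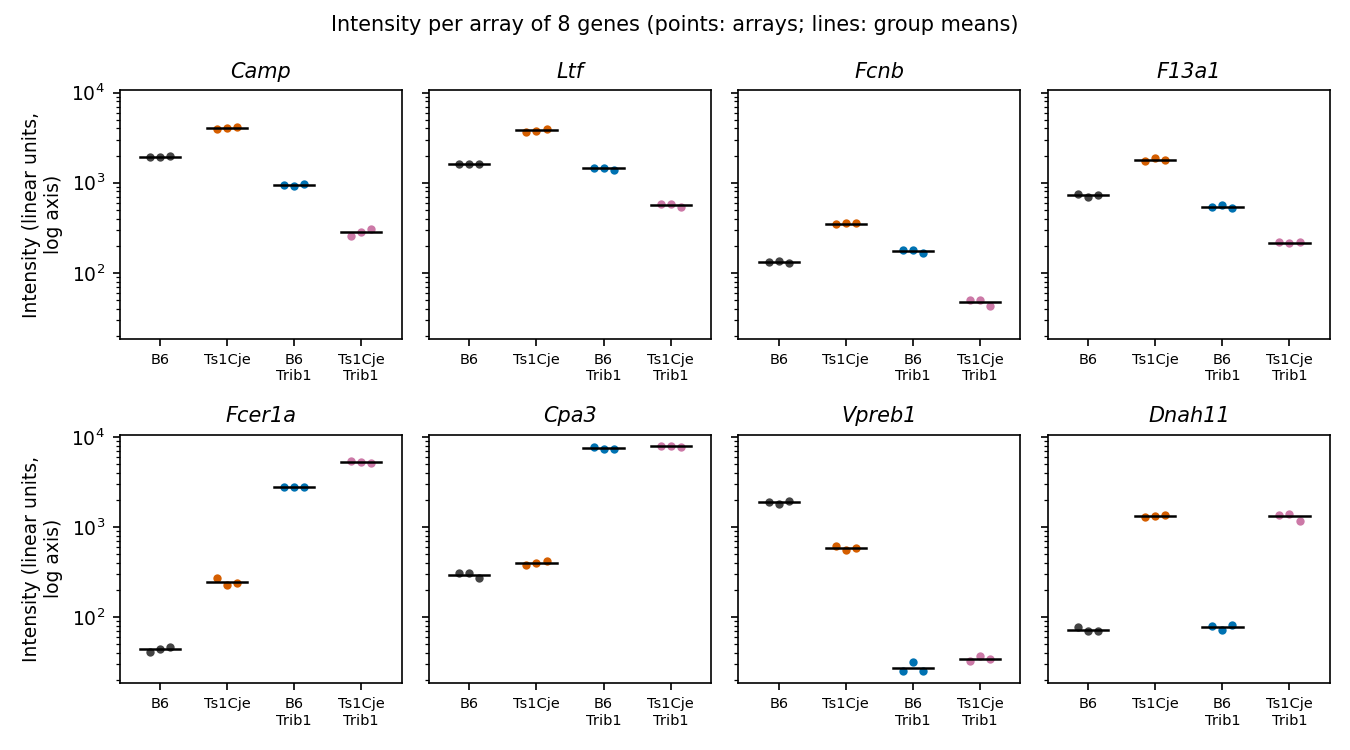
Intensity on each of the 12 arrays, on a log axis, of 8 named genes in the 4 groups; points are arrays and lines are group means. Camp had means of 1947 in B6, 4044 in Ts1Cje, 942 in B6 Trib1 and 284 in Ts1Cje Trib1.

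The interaction asked whether the genotype difference itself differed with Trib1. Lists of granule proteins, of monocytes and macrophages and of eosinophils had median genotype differences of opposite sign without and with Trib1. Other myeloid lists kept their sign: the medians were 0.35 and 0.13 for mast cells and basophils, and -0.80 and -0.26 for megakaryocytes. Across the secondary granule genes the median interaction was -1.87 with 16 of 18 genes negative among those that passed (adjusted p = 0.000281 with an estimated correlation), and across the monocyte and macrophage genes it was -1.41 with 21 of 22 negative (adjusted p = 0.000281 with an estimated correlation). Saa3, an acute-phase protein of activated macrophages, went from 441 ± 11.5 to 927 ± 30.6 without Trib1 and from 329 ± 19.1 to 57.7 ± 1.74 with it, an interaction of -3.29. The neutrophil genes Olfm4 (-3.20), Fcnb (-2.94) and Cd177 (-2.85) were also among the 6 most negative. In the other direction, Gzma fell from 329.9 ± 3.06 to 90.1 ± 15.2 without Trib1 and rose from 1039 ± 13.7 to 1626 ± 49.2 with it (2.36), and the interferon-induced GTPase Tgtp1 fell from 1028 ± 5.97 to 417 ± 5.05 and rose from 965 ± 5.61 to 1612 ± 22.8 (2.0). B cell genes had a median interaction of 1.02 (adjusted p = 0.00683 with an estimated correlation), but in both Trib1 groups Vpreb1 (27.3 ± 3.84 and 34.6 ± 2.5) and Dntt (25.8 ± 4.03 and 25.4 ± 2.36) were dim, so their genotype difference could be seen only without Trib1.

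The interaction passed for 6109 genes, 3568 positive and 2541 negative, whereas under median centring 2417 were positive and 3700 negative. Across genes, which are not independent replicates, the genotype differences without and with Trib1 had a Pearson correlation of -0.25 and a Spearman correlation of -0.26. Of the genes that rose without Trib1, 639 fell with it, where 282 would be found if the calls were unrelated, and 621 that fell without it rose with it, where 436 would be. Both differences were positive for 304 genes and negative for 247, where 347 and 354 would be found. Adjusted over the list alone, the interaction counts of the secondary granule and monocyte and macrophage lists were the same.

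Genes of the trisomic segment rose with the genotype in both settings. Of 52 measured members, 34 rose and 2 fell in Ts1Cje against B6 (median 0.23, adjusted p = 1.7e-09), and 32 rose and 1 fell in Ts1Cje Trib1 against B6 Trib1 (median 0.29, adjusted p = 2.14e-13). Rises in both were found for 24 members, without Trib1 alone for 10, with Trib1 alone for 8 and in neither for 10. The interferon receptor gene Ifnar2 rose from 731 ± 16 to 1208 ± 18.5 and from 719 ± 2.77 to 901 ± 29.3, and Psmg1, a proteasome assembly factor, rose from 834 ± 5.81 to 1053 ± 20 and from 748 ± 2.28 to 1047 ± 31.7. The median fold was 1.17 without and 1.22 with Trib1. For the 35 members with a mean intensity of at least 100 it was 1.27 in both. These folds lay below the ratio of 1.5 of the gene doses. The offset draws folds towards 1, and with an offset of 1 the log2 medians were 0.28 and 0.32. The unsettled summarisation of the values may do so too, so the shortfall cannot be read as compensation of gene dose. On chromosome 16 outside the list, 23.6% and 15.1% of 364 genes rose, against 65.4% and 61.5% in the list. Some members differed between the settings. Tmem50b rose from 783 ± 18.9 to 1598 ± 30 without Trib1 and was at 533 ± 14.6 and 513 ± 5.27 with it (interaction -1.07, adjusted p = 2.71e-09). The interleukin receptor gene Il10rb rose from 815 ± 17.1 to 1382 ± 10.8 without Trib1 and was at 277 ± 10.9 and 267 ± 8.16 with it (interaction -0.80, adjusted p = 9.82e-08). Mrps6, of the mitochondrial ribosome, rose by 0.34 and 0.86. The trisomic list as a whole did not pass for the interaction (adjusted p = 0.534), with 15 members positive and 16 negative, or 16 and 16 when adjusted over the list alone.

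On distal chromosome 12, where the extra segment is attached, Sp4, next to Dnah11, fell from 89.5 ± 3.24 to 34.5 ± 5.75 without Trib1 and Cdca7l fell from 452 ± 15.1 to 348 ± 16.4. With Trib1 their differences were -0.33 (adjusted p = 0.0461) and -0.16 (adjusted p = 0.0161). The Sp4 call with Trib1 was lost without any 1 of B6 arrays 1, 2 and 3, Ts1Cje array 2, B6 Trib1 array 3 and Ts1Cje Trib1 arrays 1 and 2 (adjusted p = 0.0564 to 0.134), and without B6 Trib1 array 3 the Sp4 difference was -0.18. The Sp4 differences with the mean of its probe sets were -0.54 without and -0.20 with Trib1. The Sp4 call was also lost with replicate number as a block, with only the groups compared, with no filter, with an offset of 1 and with a floor (adjusted p = 0.0630, 0.0759, 0.0668, 0.0576 and 0.0589). That of Cdca7l was lost without any 1 of B6 Trib1 arrays 1 and 2 and Ts1Cje Trib1 arrays 1 and 2 (adjusted p = 0.0556 to 0.0662). The distal chromosome 12 list did not pass with camera (adjusted p = 0.584 and 0.9), and its medians of -0.29 and -0.13 had the opposite sign to its means of 0.57 and 0.81. Of its 4 measured members, 3 fell and 1, Dnah11, rose without Trib1. With Trib1, 2 fell and Dnah11 rose. A test of a shared direction cannot show such a mixed change.

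**Figure D3:**
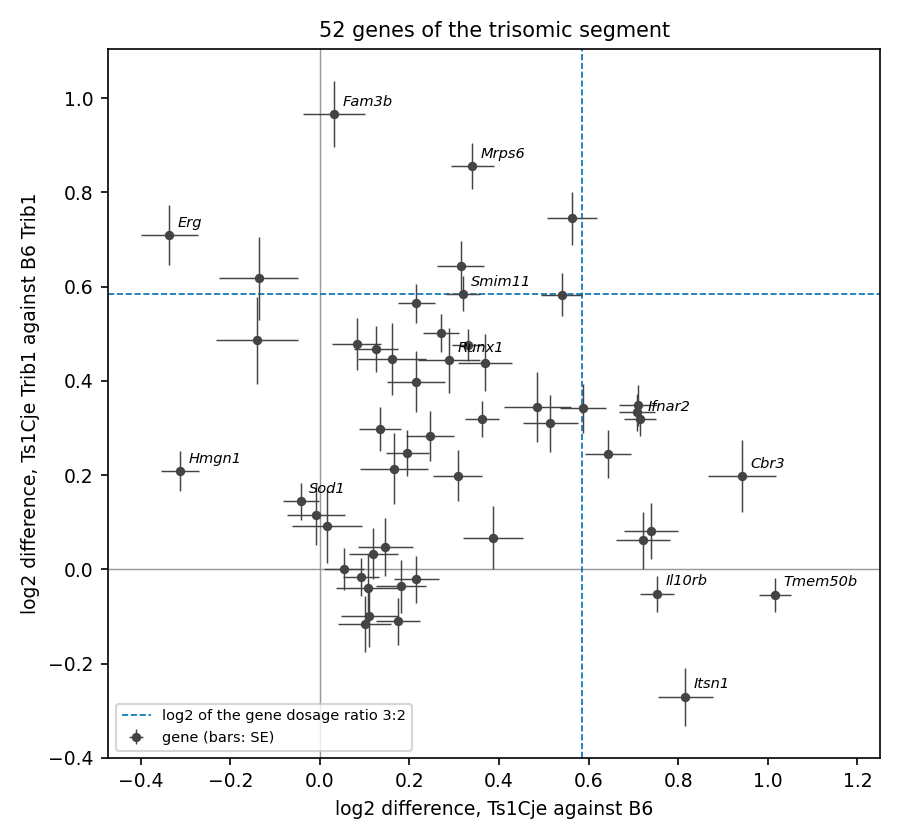
Log2 difference of each of the 52 measured genes of the trisomic segment in Ts1Cje against B6, on the horizontal axis, and in Ts1Cje Trib1 against B6 Trib1, on the vertical axis; bars are standard errors and dashed lines mark the log2 of the ratio of gene doses, 1.5. Tmem50b lies at 1.02 and -0.05, and Mrps6 at 0.34 and 0.86.

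The comparison of B6 Trib1 lines with B6 cells contrasted Trib1-expressing leukaemic cells with hematopoietic cells of the usual chromosome number. Genes of mast cells, basophils and megakaryocytes were far higher in the lines, and genes of B cells, macrophages and dendritic cells were far lower. Tph1, which starts serotonin synthesis in mast cells, rose from 38.7 ± 4.28 to 3098 ± 18.7, the mast cell protease gene Cpa3 rose from 296 ± 19.5 to 7471 ± 166, and Mycn, a MYC family gene, rose from 45.2 ± 6.98 to 3742 ± 97 in its brightest probe set. That probe set was the brightest over all arrays but the dimmest of Mycn in B6 cells. The other probe sets of Mycn were at 417 ± 3.18 and 69.8 ± 3.24 in B6 and rose by 1.02 and 0.89 on the log2 scale. The rise was 5.97 for the first, so the size of the Mycn rise was not settled. The arginase gene Arg1 fell from 4678 ± 63.7 to 21.3 ± 1.65, and the immunoglobulin light chain segment Igkj1 fell from 5703 ± 77 to 25.8 ± 2.87.

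Mast cell and basophil genes rose in 18 of 19 cases and fell in 1 (median 1.65, adjusted p = 2.47e-11), and megakaryocyte genes rose in 16 of 17 (median 1.73, adjusted p = 1.73e-09). Fcer1a rose by 5.56 on the log2 scale, and the platelet receptor genes Gp9 and Gp1bb rose by 2.85 and 2.52. Eosinophil genes rose in 4 of 6 cases (median 1.0, adjusted p = 0.00443), with the receptor Siglecf up from 22.7 ± 2.45 to 465 ± 49.9. Cholesterol synthesis genes rose in 17 of 19 cases (median 0.39, adjusted p = 2.19e-06), including Nsdhl (1.05).

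B cell genes fell in 12 of 13 cases (median -3.24, adjusted p = 3.06e-10), and Ms4a1, which encodes CD20, went from 988 ± 52.2 to 21 ± 2.42. Monocyte and macrophage genes fell in 17 and rose in 4 of 22 cases (median -1.05, adjusted p = 1.64e-06), with the mannose receptor Mrc1 down from 4147 ± 61.8 to 208 ± 19.2. Dendritic cell genes fell in 6 of 7 cases (median -1.69, adjusted p = 0.000373), including the factor Batf3 (-1.62). T and NK cell genes fell in 10 and rose in 2 of 15 cases (median -0.36, adjusted p = 0.00711), and the T cell receptor subunit gene Cd3d fell by 2.29 on the log2 scale. Among probe sets with a mean intensity of at least 100, the T and NK cell list had a median of 1.15 and did not pass (adjusted p = 0.364). Inflammatory NF-kB targets fell in 21 and rose in 7 of 29 cases (median -0.73, adjusted p = 0.000178). Socs3, a feedback inhibitor of cytokine signalling, fell by 1.79, whereas Il6 rose by 1.65. C/EBP axis genes fell in 11 and rose in 3 of 14 cases (median -0.90, adjusted p = 0.00113). The granulocyte receptor gene Csf3r fell from 379.8 ± 34.3 to 121 ± 7.87, while Cebpa, whose protein Trib1 targets, rose from 399.8 ± 13.9 to 929.7 ± 37.7. ER and integrated stress genes fell in 20 and rose in 5 of 29 cases (median -0.29, adjusted p = 0.00051), including Atf5 (-2.12).

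For further lists the call was lost with an estimated correlation, apart from MHC class II and the trisomic list, which stayed just past the threshold. MHC class II genes fell in 10 and rose in 2 of 12 cases (median -1.29, adjusted p = 0.0499 with an estimated correlation), with H2-Ab1 down from 1214 ± 57.8 to 500.3 ± 7.62. MHC class I genes fell in 6 and rose in 1 of 10 cases (adjusted p = 0.126 with an estimated correlation). Interferon response genes rose in 22 and fell in 7 of 34 cases (median 0.29, adjusted p = 0.0822 with an estimated correlation), including Usp18 (1.77). MYC and ribosome genes fell in 17 and rose in 3 of 27 cases (adjusted p = 0.271 with an estimated correlation). Replication histones rose in 5 of 7 cases (adjusted p = 0.0758 with an estimated correlation), and the linker histone gene H1f2 rose by 1.46. G2 and M phase genes rose in 16 and fell in 2 of 29 cases (adjusted p = 0.322 with an estimated correlation), and DNA replication genes rose in 15 and fell in 2 of 30 (adjusted p = 0.431 with an estimated correlation), with the helicase gene Mcm3 up from 449.8 ± 13.5 to 824 ± 40.7. The trisomic list, which carries no extra copy in B6, had 24 members that fell and 14 that rose (median -0.10, adjusted p = 0.0484 with an estimated correlation), and its median became 0.0044 under median centring.

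In total 8190 genes passed in B6 Trib1 against B6, of which 4283 were higher and 3907 lower, and 336 were at least 2-fold higher and 515 at least 2-fold lower. Median centring moved the median of all genes from 0.03 to 0.13 and gave 6356 higher and 2751 lower. With camera, 19 lists passed, 8 up and 11 down, and 13 of them passed with an estimated correlation. Adjusted over the list alone, 22 ER stress and 7 MHC class I genes fell and 4 MYC and ribosome genes rose, with the other counts for lists that passed as given. Secondary granule genes did not pass as a list (adjusted p = 0.424), with 5 members up and 9 down.

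The comparison of Ts1Cje Trib1 lines with Ts1Cje cells asked the same on the trisomic background. Mast cell and megakaryocyte genes were again higher and B cell and macrophage genes lower, and here granulocyte genes were lower as well. The carboxypeptidase gene Cpa3 rose from 399 ± 20.1 to 7813 ± 139.7 and the mast cell chymase gene Cma1 rose from 32.9 ± 2.32 to 939.7 ± 64. Cd177, a surface protein of neutrophils, fell from 2149 ± 112 to 72 ± 6.15, and C1qa fell from 1395 ± 35 to 38.7 ± 0.78.

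Secondary granule genes fell in 18 of 18 cases (median -2.06, adjusted p = 1.25e-13), with Camp down from 4044 ± 114 to 284 ± 26.1. Monocyte and macrophage genes fell in 20 and rose in 2 of 22 cases (median -2.85, adjusted p = 1.8e-13). Megakaryocyte genes rose in 17 of 17 cases (median 1.75, adjusted p = 2.02e-09), including integrin Itga2b, from 211 ± 8.63 to 1346 ± 78.1, and mast cell and basophil genes rose in 16 and fell in 1 of 19 (median 1.52, adjusted p = 2.56e-08). B cell genes fell in 12 of 13 cases (median -1.87, adjusted p = 9.98e-08), and dendritic cell genes in 6 of 7 (median -1.30, adjusted p = 0.000412). Inflammatory NF-kB targets fell in 20 and rose in 5 of 29 cases (median -0.66, adjusted p = 4.96e-06), including Ccl2, from 2754 ± 76.8 to 138 ± 19.9. MHC class II genes fell in 11 and rose in 1 of 12 cases (median -1.40, adjusted p = 1.38e-05). C/EBP axis genes fell in 10 and rose in 2 of 14 cases (median -1.39, adjusted p = 9.8e-05), with Cebpd down from 1059 ± 49.9 to 106 ± 4.04. Interferon response genes rose in 24 and fell in 4 of 34 cases (median 0.48, adjusted p = 0.000167), including the GTPase gene Igtp (1.28). ER and integrated stress genes fell in 20 and rose in 5 of 29 cases (median -0.31, adjusted p = 0.000475).

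A group of lists passed here with the preset correlation alone. CDK inhibitor and p53 genes rose in 15 and fell in 3 of 22 cases (median 0.43, adjusted p = 0.124 with an estimated correlation), and Cdkn2a, which encodes p16 and p19, rose from 12.3 ± 0.892 to 321 ± 7.33. Stem and progenitor genes rose in 14 and fell in 7 of 22 cases (median 0.84, adjusted p = 0.124 with an estimated correlation), with the factor Tal1 up from 197 ± 9.41 to 1185 ± 22. DNA replication genes rose in 22 of 30 cases (adjusted p = 0.149 with an estimated correlation), including Pola1 (0.65), and replication histones in 6 of 7 (adjusted p = 0.0873 with an estimated correlation). Primary granule genes fell in 8 and rose in 4 of 12 cases (adjusted p = 0.0509 with an estimated correlation), with Elane down from 2702 ± 47 to 257 ± 23.1. MYC and ribosome genes rose in 17 and fell in 3 of 27 cases (adjusted p = 0.36 with an estimated correlation), and the trisomic list fell in 24 and rose in 12 of 52 (adjusted p = 0.0608 with an estimated correlation). Without Ts1Cje array 2 the preset correlation gave an adjusted p = 0.0579 for the MYC and ribosome list and an adjusted p = 0.0556 for the trisomic list.

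Here 7642 genes passed, of which 4278 were higher and 3364 lower, and 523 were at least 2-fold higher and 761 at least 2-fold lower. With camera, 18 lists passed, 8 up and 10 down, and 11 of them passed with an estimated correlation. Adjusted over the list alone, 25 interferon and 23 DNA replication genes rose and 21 inflammatory genes fell, with the other counts for lists that passed as given. The Trib1 differences in the B6 and Ts1Cje backgrounds had a Pearson correlation across genes of 0.83 and a Spearman correlation of 0.64. Both were positive for 2438 genes and negative for 2471, where 1459 and 1046 would be found if the calls were unrelated. No list that passed in any comparison had a median, mean and camera direction that differed in sign.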

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

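The splits of the arrays were planned, and the tests of scaling, of Ts1Cje array 1, of cell composition, of Dnah11 and of Mycn were chosen only after the results were seen.

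The genotype difference differed with Trib1 by the interaction test for 6109 genes, 3568 positive and 2541 negative. When the genotype was relabelled within the arrays without and with Trib1, 1 of 100 draws, the real one, gave as many genes. A draw that mixes the genotypes on both sides adds their difference to the spread, so a low count was fixed in advance. The draws therefore show that the arrays of a group resemble each other. They cannot exclude chance differences between cultures or lines, because a group's arrays may be technical repeats. The highest of the other draws gave 4266 genes. All 18 other draws that gave any gene kept the true genotype split on at least 1 side of the Trib1 divide, which points to the structure of the samples. A draw with both true splits kept and the labels swapped on 1 side was allowed among them. The 81 draws that mixed both sides gave at most 0 genes with limma and 1376 at an unadjusted p under 0.05.

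By the same test, lists with a negative median interaction were those of secondary granules (-1.87), monocytes and macrophages (-1.41), eosinophils (-1.15), primary granules (-0.75), the C/EBP axis (-0.65) and cholesterol synthesis (-0.31). Positive medians were found for the lists of B cells (1.02), T and NK cells (0.73), MYC and ribosome biogenesis (0.44), stem and progenitor cells (0.39) and interferon response (0.28). With Trib1 the genotype medians of the B cell, T and NK cell, MYC, and stem and progenitor lists were -0.01, -0.04, 0.07 and 0.01. Their interactions mostly mirror falls without Trib1 (-1.10, -0.80, -0.40 and -0.39). The cholesterol interaction mirrors a rise without Trib1 (0.30, against 0.0042 with it). The lists of DNA replication (0.18), MHC class I (0.23), glycolysis (-0.21), inflammatory NF-kB targets (-0.17), mast cells and basophils (-0.13) and hypoxia (-0.13) passed with the preset correlation alone, at an adjusted p = 0.288, 0.101, 0.219, 0.19, 0.19 and 0.219 with an estimated correlation. The hypoxia call was lost without Ts1Cje array 1, B6 Trib1 array 3 or Ts1Cje Trib1 array 3 (adjusted p = 0.0904, 0.0812 and 0.0503), the inflammatory call without Ts1Cje array 1 (adjusted p = 0.0619), and the mast cell call without B6 Trib1 array 3 or Ts1Cje Trib1 array 3 (adjusted p = 0.0522 and 0.0508).

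Among genes, the largest positive interactions were those of Gzma (2.36), Vpreb2 (2.19), Trgv1 (2.02), Tgtp1 (2.0), Enpep (1.91) and Vpreb1 (1.89). For Vpreb1, Vpreb2 and Enpep both Trib1 groups were dim, with means of 27.3 ± 3.84 and 34.6 ± 2.5, 19.2 ± 2.41 and 21.8 ± 2.82, and 30.8 ± 1.07 and 26.1 ± 2.14. The largest negative ones were those of Saa3 (-3.29), Olfm4 (-3.20), Ceacam10 (-3.18), Fcnb (-2.94), Hp (-2.89) and Cd177 (-2.85).

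Of 8477 probe sets without a single gene symbol, which no comparison of named genes used, 3697 passed in Ts1Cje against B6, 994 in Ts1Cje Trib1 against B6 Trib1, 4850 in B6 Trib1 against B6 and 3798 in Ts1Cje Trib1 against Ts1Cje. These counts were adjusted over all kept probe sets, with or without a single symbol.

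For each pairwise comparison, 1 of the 10 splits of its 6 arrays, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real and highest other counts with limma were 6602 and 0 for Ts1Cje against B6, 2698 and 0 for Ts1Cje Trib1 against B6 Trib1, 8190 and 0 for B6 Trib1 against B6, and 7642 and 0 for Ts1Cje Trib1 against Ts1Cje. At an unadjusted p under 0.05 the highest other counts were 1266, 1243, 529 and 1002.

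Of the 40 secondary granule, monocyte and macrophage genes, 35 rose in Ts1Cje against B6, 34 fell in Ts1Cje Trib1 against B6 Trib1, and 30 did both, with a median interaction of -1.47. Under quantile normalization and median centring the value nearest 0 was -1.49, and without Ts1Cje array 1 the median was -1.44. Neither rerun could have changed this median much. Median centring moved the median interaction of all genes only from 0.008 to -0.083, and Ts1Cje array 1 had a correlation of 0.997 with Ts1Cje array 2. That correlation was still the lowest of any pair within a group. Without Ts1Cje array 1 the genes that passed with limma in Ts1Cje against B6 went from 6602 to 7200. What the values show is that differences of scale between these arrays were too small for a pattern of this size. A larger share of mature myeloid cells that diluted every other cell type alike in Ts1Cje was compared with mast cell and B cell markers. If mast cells were among the diluted cells, both sets would fall by like amounts. Their means were 0.32 and -1.10, a difference of 1.42. Mast cells and basophils are themselves myeloid and may belong to the larger share. The difference therefore cannot decide the question, and such a dilution stays open. A permutation test over 19 and 13 genes gave p = 1e-05, the smallest that 99999 resamples can give. That p-value adds no support, because genes are not independent and both lists had been seen before the test was chosen. With camera the mast cell call was lost with an estimated correlation (adjusted p = 0.0605). A change in several cell types at once, or lines that differ for reasons other than the trisomy, stays open and was not tested. A candidate explanation is that the trisomy itself may favour myeloid maturation without Trib1 and not in the leukaemic lines, which these tests cannot separate from those.

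Dnah11 was at least 1172 on each of 6 arrays with the trisomy and at most 81.8 on each of 6 without it. Dnah11 was picked for having the largest rise, so an excess over the log2 of the ratio 1.5 was known before it was tested. That excess was at least 3.24 (standard error 0.0654), which argues against a rise in proportion to an extra gene copy. An effect of trisomic genes on Dnah11 stays open. Of the 10 nearest measured neighbours, 9 were centromeric. A disturbed stretch of chromosome 12 across these in both comparisons is argued against, since 1 of the 9, Cdca7l, changed the same way in both. Zfp386 (-0.45, adjusted p = 0.000855) and Esyt2 (0.28, adjusted p = 0.00015) also passed without Trib1, where 52.6% of all genes did. With Trib1 they did not pass (adjusted p = 0.135 and 0.221). Asking for a change in both comparisons does not bear on a disturbance seen without Trib1 alone. A disturbed stretch on the telomeric side cannot be told apart from other causes, since Sp4, which fell in both, was the 1 measured gene there. The calls with Trib1 of Sp4 and Cdca7l (adjusted p = 0.0461 and 0.0161) were lost when any 1 of several arrays was left out. That of Sp4 was also lost under several other alternatives. A short stretch around Dnah11 may remain too, because Cdca7l, the nearest centromeric gene, fell as well (-0.37 without and -0.16 with Trib1). The next, Rapgef5, had differences of -0.21 and -0.09 (adjusted p = 0.0131 and 0.355), and its call without Trib1 was lost under quantile normalization (-0.15, adjusted p = 0.0672), under median centring (-0.13, adjusted p = 0.0883) and without Ts1Cje array 3 (adjusted p = 0.0614). Whether the probe set reads a whole Dnah11 transcript was not tested.

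Mycn rose by 5.97 and 5.92 on the log2 scale with Trib1 in the brightest probe set. All Mycn transcript rising alike is argued against, because the other probe sets of Mycn rose by between 0.89 and 3.10. The rise of 3.10 was in the Ts1Cje background, where that probe set started from a lower mean of 106, against 417 in B6 (-1.85). The further probe sets, including the brightest, differed by -0.60 and 0.10 between Ts1Cje and B6 cells. A sequence shared by both Trib1 lines, such as a part of the expression vector or an inserted copy, cannot be told apart from an increase of one transcript form, since 8.70% of the 69 genes that rose over 4-fold in both backgrounds differed less between the lines than Mycn, and no probe sequences were at hand. No biological explanation was tested for this pattern.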

How the results depend on the processing

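Leaving out Ts1Cje array 1 and B6 Trib1 array 3 together, and keeping only probe sets with a mean intensity of at least 100, were chosen after seeing the data. Of 328 values of the main results under the alternatives, 325 kept their direction and side of the threshold, or for a count stayed within 1.5 times the count reported. With an estimated correlation in camera, the lists that passed went from 21 to 9 in Ts1Cje against B6 and from 18 to 11 in Ts1Cje Trib1 against Ts1Cje. With a mean intensity of at least 100, the genes that passed in B6 Trib1 against B6 went from 8190 to 5343, because fewer genes were tested. Of 2245 values of the lists, 2161 kept their direction and call, 82 lost the call and 2 reversed. The reversed ones were both in B6 Trib1 against B6: the trisomic list had a median of 0.0044 under median centring, and the T and NK cell list a median of 1.15 (adjusted p = 0.364) at a mean intensity of at least 100, which left few of its members. Of 9556 values of named genes, 9523 kept their direction and call, 25 lost it, 7 gained it and 1 reversed, which was Tyms in B6 Trib1 against B6 at -0.0901 without cross-hybridizing probe sets, where another probe set stands for the gene. Leave-one-out fits gave 5552 to 7200 genes for Ts1Cje against B6, 2056 to 2972 for Ts1Cje Trib1 against B6 Trib1, 7178 to 8531 for B6 Trib1 against B6, 7178 to 7714 for Ts1Cje Trib1 against Ts1Cje and 5316 to 6859 for the interaction. With the replicate number as a block, the counts were 6352, 2485, 8017, 7519 and 5818, and with both arrays left out together they were 7494, 3446, 8554, 7849 and 7234. Median centring moved the share of higher genes from 44.3% to 65.0% in Ts1Cje against B6, from 52.3% to 69.8% in B6 Trib1 against B6, and of positive interactions from 58.4% to 39.5%, so the balance of directions depends on the scaling. Genes near the arrays' 40th percentile are limited by background, where differences between dim groups cannot be read.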

Other observations

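The MAPK feedback list did not pass in either comparison of Trib1 lines with cells without Trib1 (B6 Trib1 against B6, 15 rose and 7 fell of 25, adjusted p = 0.077; Ts1Cje Trib1 against Ts1Cje, 12 and 5, adjusted p = 0.0644). The MAPK counts were 15 up and 7 down, and 15 up and 5 down, when adjusted over the list alone. Members went both ways, between -2.21 and 4.09 in B6 Trib1 and between -1.55 and 4.09 in Ts1Cje Trib1. The lowest was the cyclin gene Ccnd1 in both, and Egr2 also fell (-0.81 and -1.14). Ccnd1, Egr2, Lif and Fos were chosen here after their values were seen. Lif and Fos had means of 79.6 ± 3.85 and 103 ± 7.19 without Trib1 and 1599 ± 54.4 and 1987 ± 56.5 with it for the cytokine gene Lif, and of 282 ± 14.5 and 315 ± 17.3 and then 1191 ± 21.6 and 1119 ± 37.9 for the transcription factor gene Fos. Egr1, an immediate early gene named under the rule, went from 535 ± 2.82 to 2479 ± 53.4 and from 492 ± 19.5 to 2423 ± 53.9. In the BCL2 family list, the survival gene Bcl2, also chosen after its values were seen, was at 427 ± 5.56 and 239.8 ± 14.9 without Trib1 and at 930.1 ± 47.8 and 1217 ± 39.4 with it. That list did not pass in any pairwise comparison, at an adjusted p = 0.804 in Ts1Cje against B6 (median -0.04), 0.351 with Trib1 (-0.03), 0.636 in B6 Trib1 against B6 (0.16) and 1 in Ts1Cje Trib1 against Ts1Cje (0.11).

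Oxidative phosphorylation genes differed little between the genotypes, where 2 of 28 rose and 1 fell without Trib1 and 1 rose with it (adjusted p = 0.804 and 0.9). Against cells without Trib1, 12 fell and 3 rose in B6 Trib1 and 14 fell and 3 rose in Ts1Cje Trib1 (adjusted p = 0.0734 and 0.0644). When adjusted over the list alone, 1 rose and 0 fell between the genotypes without Trib1 and 11 fell in B6 Trib1, with the other oxidative phosphorylation counts the same. The IL-3 and STAT5 list did not pass in any pairwise comparison (adjusted p = 0.269, 0.351, 0.564 and 0.289 in the order used above, medians -0.06, 0.07, 0.12 and 0.28), and in B6 Trib1 against B6 its mean of -0.01 had the opposite sign to its median. The HOX and MEIS list did not pass either (adjusted p = 0.241, 0.351, 0.636 and 0.981, medians -0.09, -0.08, 0.11 and -0.09), and in Ts1Cje Trib1 against Ts1Cje its mean of 0.20 was opposite in sign to its median.

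Transcripts of the X-inactivation gene Xist and of the Y-linked genes Kdm5d and Eif2s3y, the last pair chosen after their values were seen, were present in all 4 groups. Xist was at 1319.8 ± 5.94 in B6, 1093 ± 20 in Ts1Cje, 784 ± 14.2 in B6 Trib1 and 2071 ± 98 in Ts1Cje Trib1. Kdm5d was at 160.2 ± 3.84, 137 ± 11.4, 216 ± 3.65 and 178 ± 6.39, and Eif2s3y at 534 ± 23.5, 449 ± 36.1, 558 ± 42.6 and 395 ± 15.2. The sex-linked list did not pass in any pairwise comparison with camera (adjusted p = 0.0899, 0.9, 0.739 and 0.218). With Trib1 its median between the genotypes was -0.14 and its mean 0.15, and 1 member rose and 2 fell. Shares of male and female cells that differed would move Xist and the Y-linked genes in opposite directions. A list test of a shared direction cannot show this, so a difference in sex between the groups stays open. The labels give no sex.

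Deviations of Ts1Cje array 1 and B6 Trib1 array 3 from their group means had a correlation across genes of 0.60, the highest of any pair of arrays in different groups. Of the genes with several kept probe sets, 120 had probe sets called in both directions in Ts1Cje against B6, 4 in Ts1Cje Trib1 against B6 Trib1, 417 in B6 Trib1 against B6 and 109 in Ts1Cje Trib1 against Ts1Cje.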
